A study of Mus musculus with 15 samples.

How the data were processed

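Total RNA of mouse colon was extracted with Trizol and biotin-labelled cRNA was hybridised to Affymetrix Mouse430_2 arrays, per the labels' protocols. The deposited table holds log2 values made with RMA, per the submitters' processing notes, which also name Partek 6.5. The log2 scale was read from the values, which run from 2.56 to 14.7 with array medians from 6.34 to 6.46. RMA summarises probes into probe sets and quantile normalizes the arrays together, so it forces the arrays to a common distribution, and a shift that affects most genes one way is largely removed. The genome build and detection calls are not given in the sources used here. From these values everything below was computed anew.

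Of 45101 probe sets 64 are controls. The platform annotation gave 34945 probe sets with 1 gene symbol, 932 with several and 9160 with none, and those with several or none were left out. Updating symbols through the Entrez identifier against the assembly GRCm38.p6 changed 0 symbols. The probe set with the highest mean over all 15 arrays was kept for each of 18193 genes, of which 9010 had more than 1, and 1745 of those kept carry the suffix of probe sets that can match several transcripts. No filter on dim genes was applied. Probe sets of a gene can disagree, as for Apc.

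Groups were taken from the genotype and tissue labels. A model with 5 group means was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), and 8 contrasts were tested with Benjamini-Hochberg adjustment within each over all genes, at an adjusted p of 0.05. The interaction is adjacent minus APC mutant, less Olfm4 mutant minus wild type. Adjusted p-values of genes are from limma throughout, those of single Apc and Olfm4 probe sets over all probe sets where a probe set other than the kept one is quoted. Standard errors (SE) are those of the fitted log2 difference, 3 arrays against 3. The 31 gene lists (525 entries, 476 measured) were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. The members called were counted over all genes and adjusted over the list alone. Some lists share members, so their results are not separate. Also held by another list were 8 of 28 Wnt target, 7 of 19 stem cell and 4 of 19 antimicrobial genes. The same held for 3 of 13 neutrophil, 3 of 12 protease and 2 of 5 Paneth cell genes. Groups, contrasts, lists, the rule for named genes and all alternatives except those with the spike-in covariate and the blocked list tests were set before the data were examined. The rule named Olfm4 and Apc, the 10 highest and 10 lowest fold changes among called genes whose arrays do not overlap between groups (predicted symbols could be skipped), up to 4 members per list described, and 11 fixed genes for tumour against adjacent tissue. Genes outside that rule stand in the closing section and were chosen after their values were seen.

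The 3-prime minus 5-prime difference of control probe sets was taken per array as the mean over the 4 added bacterial RNAs dap, lys, phe and thr, and was also used as a covariate in the same model. Alternatives were the mean of all probe sets or the most variable probe set per gene, only genes above the median mean of 8.39, cyclic loess normalization, a trend and robust prior, array weights, only the groups compared, a fold change of at least 1.5, each array left out in turn, animal as a random block, arrays of an animal averaged, and replicate blocks. The adjacent and tumour arrays come from the same animals by their titles, and pairs were formed by replicate number. Replicates 2 and 3 share an animal, and the titles do not state which of its adjacent pieces belongs with which tumour piece. Deviations from the group means over genes correlated at 0.281, -0.0155 and 0.182 for pairs 1, 2 and 3, at 0.124 and 0.126 between the other arrays of the shared animal, and from -0.259 to -0.0881 between animals.

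The fit was tested on simulated data of 18193 genes with 200 changed. For tumour against adjacent tissue it recovered 55% of genes changed by a log2 of 1 and 97% of those changed by 2, or 21% and 74% with the spike-in covariate. For adjacent against wild type it recovered 62% and 96%, or 0% and 22% with the covariate, because the covariate nearly coincides with the groups. For Olfm4 mutant against wild type it recovered 64% and 94%, or 44% and 84% with the covariate. For tumour against wild type it recovered 64% and 95%, or 0% of either with the covariate. Where 200 simulated genes followed the spike-in difference without a group effect, 147 were called in adjacent against wild type and 197 in tumour against wild type without the covariate, and 0 with it. Without the covariate 147 were called in adjacent against APC mutant and 52 in adjacent against Olfm4 mutant. In Olfm4 mutant and APC mutant against wild type and in tumour against adjacent 0 were called. This holds for the simulated slopes and number of genes only. Replicates of a group correlated at 0.972 to 0.995 over genes and no pair held identical tables. The first principal component took 60.4% of the variance and the second 12.5%.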

Results

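Gene expression was measured in 15 colon samples of male mice aged 3 months, on Affymetrix Mouse430_2 arrays, with 3 arrays in each of 5 groups. The mice were littermates on a hybrid background that includes C57BL/6. The groups were wild type colon, colon with a heterozygous APC mutation, colon lacking Olfm4, and, from mice carrying both mutations, tissue next to a tumour (adjacent tissue) and tumour tissue. Apc is the scaffold that marks beta-catenin for breakdown and so restrains Wnt signalling, and Olfm4 is a secreted glycoprotein of intestinal crypts and neutrophils. The labels state 3 mice per category, while the double mutant titles carry 2 animal numbers, one of which accounts for 2 of the 3 arrays in each of the adjacent and tumour groups. The title of Olfm4 mutant replicate 3 carries a number that joins digits of the other animals of its group. P-values therefore measure the spread between these samples, part of which can be technical. The number of arrays limits the precision, and the deposited values carry no detection call.

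The targeted genes come first. The only Olfm4 probe set lay near the floor of the array in every group, from 2.97 to 3.32 over the 15 arrays on the log2 scale, with a wild type mean of 3.07 ± 0.067 (SD, n = 3) and an Olfm4 mutant mean of 3.11 ± 0.15. It therefore gives no check of the Olfm4 genotype. Apc had several probe sets that moved apart. The brightest was 0.43 higher in APC mutant than in wild type colon (SE 0.12, adjusted p = 0.53), and 0.64 higher in double mutant adjacent than in wild type colon (SE 0.12, adjusted p = 0.0026). Another Apc probe set was lower than in wild type by 2.00 in adjacent tissue (adjusted p = 0.00035) and by 1.29 in Olfm4 mutant colon (adjusted p = 0.018), whose Apc is intact. It stood at -0.06 in APC mutant colon (adjusted p = 0.98). Its means fell from 8.43 in wild type through 8.37 in APC mutant, 7.14 in Olfm4 mutant and 6.42 in adjacent to 6.21 in tumour arrays. That is the order in which the spike-in difference described below rises. A further Apc probe set, nearly as bright as the first (wild type mean 10.44), stood at 0.05 in APC mutant colon (adjusted p = 0.95). Where these probe sets lie relative to the mutated part of Apc was not established here, so they check nothing either.

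The bacterial RNAs added before labelling, which have the same sequence on every array, differed between the groups. The mean difference between their 3-prime and 5-prime probe sets was 1.99 ± 0.0832 (SD, n = 3) on the log2 scale in wild type, 2.16 ± 0.203 in APC mutant, 2.64 ± 0.525 in Olfm4 mutant, 4.10 ± 0.3 in adjacent and 5.01 ± 0.255 in tumour arrays. Gapdh and Actb, the housekeeping genes with matching probe sets, moved the same way, with Gapdh differences of 0.589 in wild type, 3.97 in adjacent and 4.57 in tumour arrays. The spike-in difference followed the number of the array in the run over the 15 arrays (Pearson r = 0.93, Spearman rho = 0.968, 2-sided permutation p = 0.00001 for each, the smallest that 100000 permutations can give). Without the 2 arrays farthest from the median of array number r was 0.93. Array numbers run through the groups in blocks, so the run order and the group cannot be told apart, and no correlation within a group of 3 was computed.

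**Figure D1:**
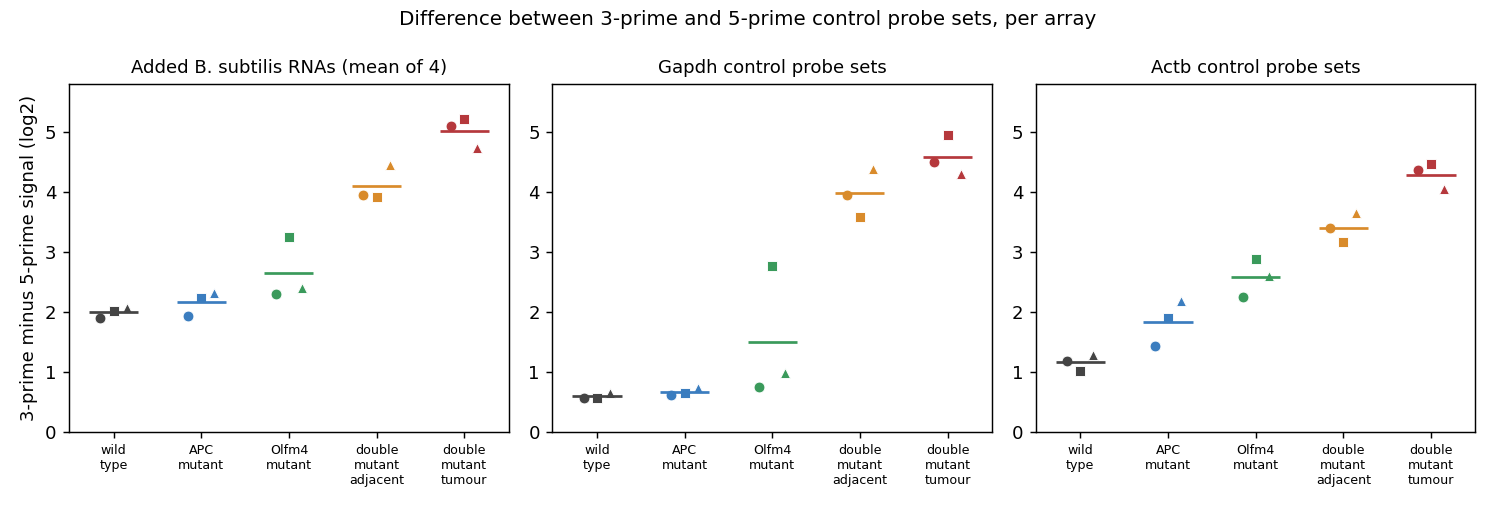
Each panel plots, for each of the 15 arrays, the 3-prime minus 5-prime signal in log2 units of control probe sets (mean of the 4 added bacterial RNAs, Gapdh and Actb) against the group, with a line at each group's mean and circle, square and triangle for replicates 1, 2 and 3. The added RNAs have means of 1.99 in wild type, 2.16 in APC mutant, 2.64 in Olfm4 mutant, 4.10 in adjacent and 5.01 in tumour arrays.

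Tumours of double mutant mice were first set against adjacent tissue of the same mice, which asks how tumour and neighbouring colon differ. Wnt target genes were higher in the tumours. Wnt10a, a Wnt ligand, was 74.7-fold higher (log2 6.22, SE 0.44, n = 3 per group, adjusted p = 8.5e-07). Axin2, the negative feedback regulator of the pathway, rose by 1.97 on the log2 scale (SE 0.17, adjusted p = 4.9e-06), and Lgr5, the R-spondin receptor of crypt base stem cells, by 2.83 (SE 0.23, adjusted p = 2.5e-06). Genes of differentiated colon cells were lower, among them the carbonic anhydrase Car4 of absorptive cells by 10.3-fold (log2 -3.37, SE 0.11, adjusted p = 5.7e-09) and the intermediate filament desmin (Des) of smooth muscle by 20.7-fold (log2 -4.37, SE 0.47, adjusted p = 2.2e-05). By limma, 5112 of 18193 genes (28.1%) passed an adjusted p of 0.05, 2607 higher and 2505 lower. Of these, 1198 higher and 1333 lower differed by a fold change of at least 2.

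In the Wnt/beta-catenin target list 23 of 28 measured genes rose and 0 fell (24 rose adjusted over the list alone), with a median of 2.03 (camera adjusted p = 3.8e-14, and adjusted p = 0.026 with an estimated correlation). Besides Wnt10a, Axin2 and Lgr5, the transcription factor Sp5 was 17.7-fold higher (log2 4.14, SE 0.38). Of the intestinal stem cell list 13 of 19 genes rose and 2 fell (15 and 2 adjusted over the list alone, median 1.24, camera adjusted p = 2.1e-08, adjusted p = 0.073 with an estimated correlation). Of these 19 genes 7 also stand in another list, as do 8 of the 28 Wnt targets, so the results overlap. The RNA-binding proteins Mex3a and Msi1 rose by 3.29 (SE 0.28) and 3.08 (SE 0.25), and the telomerase subunit Tert by 2.78 (SE 0.13). The stem cell factor Ascl2 was 2.24 higher (SE 0.69, adjusted p = 0.027), a call that ended when any of the 6 arrays was left out (adjusted p from 0.052 to 0.083). Cell cycle genes moved by less, with 19 of 29 higher and 0 lower (22 higher adjusted over the list alone, median 0.84, camera adjusted p = 5.3e-09, adjusted p = 0.21 with an estimated correlation). The replication licensing genes Cdc6, Mcm2 and Mcm7 rose by 2.06 (SE 0.23), 1.48 (SE 0.2) and 1.12 (SE 0.17), and cyclin D1 (Ccnd1) by 0.72 (SE 0.18, adjusted p = 0.0077). Myc at 0.77 (SE 0.39, adjusted p = 0.17) and the proliferation marker Mki67 at 0.44 (SE 0.25, adjusted p = 0.23) did not pass.

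Of the absorptive colonocyte list 16 of 20 genes fell and 1 rose (17 and 1 adjusted over the list alone, median -2.32, camera adjusted p = 3.8e-14, adjusted p = 0.026 with an estimated correlation). The largest fall was that of the cytochrome Cyp2c55, 45.8-fold (log2 -5.52, SE 0.35). The water channel Aqp8 fell by 3.71 (SE 0.22), the sulfate transporter Slc26a2 by 2.44 (SE 0.094) and the carbonic anhydrase Car1 by 1.58 (SE 0.18). Goblet cell genes fell in 12 of 15 cases and none rose (14 adjusted over the list alone, median -1.52, camera adjusted p = 2e-07, adjusted p = 0.21 with an estimated correlation). The secreted mucin Muc2 was 1.98 lower (SE 0.45, adjusted p = 0.0054), the goblet cell transcription factor Spdef 2.64 lower (SE 0.42) and the trefoil peptide Tff3 1.06 lower (SE 0.17). Enteroendocrine genes fell in 11 of 16 cases and rose in 1 (11 and 1 adjusted over the list alone, median -1.84, camera adjusted p = 1.3e-06, adjusted p = 0.2 with an estimated correlation). The hormone genes Insl5, Gcg (glucagon) and Sst (somatostatin) changed by -4.32 (SE 0.28), -3.61 (SE 0.26) and -2.78 (SE 0.28). In the Paneth cell list 3 of 5 genes rose (3 adjusted over the list alone, median 2.46, camera adjusted p = 0.045, adjusted p = 0.25 with an estimated correlation). They were the protease Mmp7 at 4.52 (SE 0.9), lysozyme Lyz1 at 0.45 (SE 0.14) and the lectin Itln1 at 2.46 (SE 0.84, adjusted p = 0.043). Itln1 had an adjusted p = 0.052 with animal as a block and 0.054 in a pairing block. The list lost its call without adjacent replicate 2 (median 1.66, adjusted p = 0.14) or tumour replicate 1 (2.07, 0.069), 2 (2.23, 0.06) or 3 (2.5, 0.052).

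Genes of the muscle wall were lower in the tumours. Of the smooth muscle list 15 of 16 fell (16 adjusted over the list alone, median -3.07, camera adjusted p = 1.7e-11, adjusted p = 0.21 with an estimated correlation), with phospholamban (Pln) at -4.19 (SE 0.5) and the myosin light chain Myl9 at -3.19 (SE 0.33). Enteric neuron and glia genes fell in 10 of 17 cases (11 adjusted over the list alone, median -1.23, camera adjusted p = 2.4e-04, adjusted p = 0.39 with an estimated correlation). The neuropeptide Vip was 69.6-fold lower (log2 -6.12, SE 1.1), with a mean of 5.75 ± 3.3 (SD, n = 3) in the tumours against 11.9 ± 0.26 in adjacent tissue, and the glial transcription factor Sox10 was lower by 2.67 (SE 0.45).

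Immune and matrix genes split by kind. B cell genes fell in 11 of 12 cases (12 adjusted over the list alone, median -2.62, camera adjusted p = 1.3e-06, adjusted p = 0.21 with an estimated correlation), with the B cell receptor chains Cd79a and Cd79b lower by 2.57 (SE 0.42) and 3.01 (SE 0.47). In adjacent tissue some of these genes stood above wild type colon, Cd22 by 2.12, Cr2 by 2.11, Fcmr by 3.00 and Fcer2a by 1.19. In the tumours they fell by 2.09, 2.67, 3.60 and 1.23, so their fall starts from that raised level. Not all members were called in adjacent against wild type, and B cell genes did not pass as a list there. Of the plasma cell list 8 of 11 fell and 1 rose (8 and 2 adjusted over the list alone, median -1.28, camera adjusted p = 2.6e-04, adjusted p = 0.21 with an estimated correlation), including Irf4 at -2.41 (SE 0.26) and Mzb1 at -2.39 (SE 0.27). Neutrophil genes rose in 9 of 13 cases (10 adjusted over the list alone, median 1.57, camera adjusted p = 3e-04, adjusted p = 0.25 with an estimated correlation), among them the lectin receptor Clec4e at 3.32 (SE 0.48) and the chemokine receptor Cxcr2 at 2.05 (SE 0.47). Of the NF-kappaB and cytokine list 14 of 28 rose and 1 fell (16 and 3 adjusted over the list alone, median 0.97, camera adjusted p = 3.5e-04, adjusted p = 0.25 with an estimated correlation). Il23a was 15.2-fold higher (log2 3.93, SE 0.26), Tnf rose by 1.44 (SE 0.2) and the chemokine Cxcl1 by 2.66 (SE 0.62). Il1b at 2.14 (SE 0.88, adjusted p = 0.092) and the prostaglandin synthase Ptgs2 at 1.29 (SE 0.57, adjusted p = 0.11) did not pass. Proteases and matrix remodelling genes rose in 9 of 12 cases (10 adjusted over the list alone, median 2.88, camera adjusted p = 3.7e-06, adjusted p = 0.21 with an estimated correlation), with the hyaluronidase Cemip at 3.41 (SE 0.4) and the membrane protease Mmp14 at 1.48 (SE 0.2).

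The other genes with the largest rises were the proton channel Otop1 (5.87, SE 0.76), Clstn2 (5.59), the mast cell receptor chain Ms4a2 (5.54), the zinc transporter Slc30a2 (5.42), Gprin2 (5.39), the transcription factor Onecut2 (5.08), Erich3 (5.01), the tight junction gene Cldn6 (5.00) and the Lgr5 relative Lgr6 (4.99). The largest falls also took in the synaptic gene Rims1 (-5.35), the transcription factor Foxp2 (-4.81), the potassium channel Kcnd3 (-4.76), the immunoglobulin chain Ighg3 (-4.75), the urea cycle enzyme Otc (-4.59) and the antisense RNA Hoxb5os (-4.57). In each of these genes the 3 tumour arrays lay beyond all 3 adjacent arrays, as the rule for naming them requires. The remaining 17 of the 31 lists did not pass, with camera adjusted p from 0.062 for circadian clock genes (0.044 with animal as a block or in a pairing block) to 0.98 for interferon response, fibroblast and matrix, posterior HOX, and epithelial antimicrobial genes. Among these were small intestine genes at 0.12, adipocyte at 0.14, regeneration and fetal epithelium at 0.31, fatty acid oxidation at 0.34, macrophage at 0.54, erythroid at 0.56, tuft cell at 0.57, T cell, exocrine pancreas, sex-linked, and immediate early and heat shock genes at 0.64 each, and endothelial genes at 0.66.

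The spike-in difference rose from 4.10 in adjacent to 5.01 in tumour arrays, beside each of these gene groups. With it as a covariate 2144 genes were called, 2025 of them among the original 5112 in the same direction (39.6%). Of the 5112 genes 99.9% kept their sign. Their median absolute log2 fold change went from 0.993 to 0.929 and their median SE from 0.205 to 0.305, so the calls ended mostly through the wider error. Of the smooth muscle genes 13 then fell, of the absorptive genes 15, and of the Wnt targets 15 rose, against 2 cell cycle, 2 B cell and 1 neutrophil gene. Averaging arrays of the same animal and tissue, which leaves 2 animals per group, gave 3286 called genes.

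**Figure D2:**
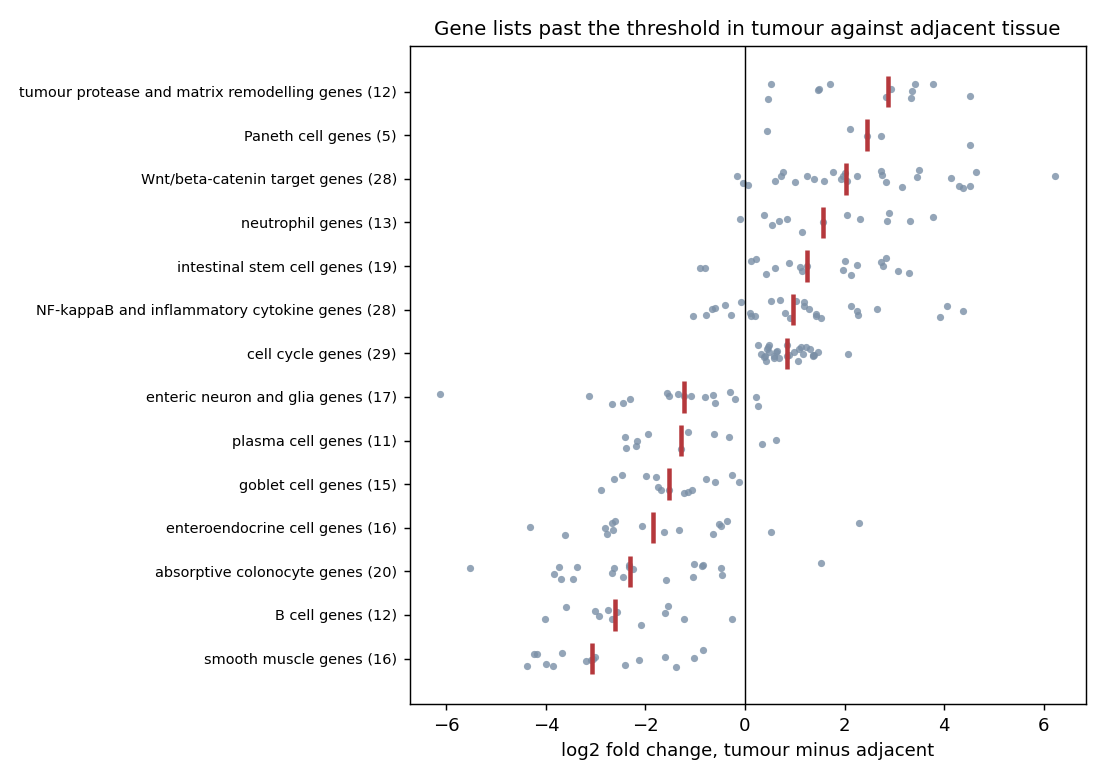
Each point is a measured gene of a list, at its log2 fold change of double mutant tumour minus adjacent tissue (3 arrays each), and the bar marks the list's median, for the 14 lists past a camera adjusted p of 0.05, with the number of genes in brackets. The medians run from -3.07 for smooth muscle genes to 2.88 for proteases and matrix remodelling genes.

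Tumours were also set against wild type colon. The Wnt antagonist Wif1 was 222-fold higher (log2 7.80, SE 0.73, n = 3 per group, adjusted p = 3e-06), Wnt10a 176-fold (log2 7.46, SE 0.44) and Sox2, a transcription factor of foregut and neural tissue, 121-fold (log2 6.92, SE 0.79). Wild type means were low, 4.17 ± 0.19 (SD) for Wif1 and 4.81 ± 0.69 for Sox2 on a scale that starts at 2.56. Without a detection call it is not known whether these genes stood above background in wild type. The groups also differ in the spike-in difference, so the size of such folds is uncertain. Aqp8 was 59-fold lower (log2 -5.88, SE 0.22, adjusted p = 6.7e-09) and the fatty acid carrier Fabp2 56-fold lower (log2 -5.81, SE 0.48). The other largest rises were Otop1 (8.48), Slc30a2 (7.49), the pancreatic lipase relative Pnliprp1 (7.45), Ms4a2 (6.88), Erich3 (6.84), Sox11 (6.82) and the chemokine Cxcl2 (6.62). The other largest falls were Cyp2c55 (-6.43), the retinol carrier Rbp2 (-5.98), Vip (-5.93), Otc (-5.79), Rabac1 (-5.63), Aadac (-5.46), Insl5 (-5.41) and Rims1 (-5.32). By limma 8996 genes passed (49.4%), 5334 higher and 3662 lower, or 4485 and 4438 after an added cyclic loess normalization, which moved the median of all genes from 0.11 to -0.01.

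Absorptive colonocyte genes fell in 18 of 20 cases (18 adjusted over the list alone, median -2.37, camera adjusted p = 4.1e-13, adjusted p = 0.038 with an estimated correlation). Wnt target genes rose in 25 of 28 (26 adjusted over the list alone, median 2.78, camera adjusted p = 2.9e-10, adjusted p = 0.077 with an estimated correlation). Smooth muscle genes fell in 15 of 16 (16 adjusted over the list alone, median -3.21, camera adjusted p = 2.3e-09, adjusted p = 0.35 with an estimated correlation). In all 16 lists passed by camera, 6 higher and 10 lower, of which the absorptive list kept its call with an estimated correlation. The spike-in difference was 1.99 in wild type and 5.01 in tumour arrays. With it as a covariate 1 gene was called, Car4 (log2 -3.84, adjusted p = 0.032). For the genes called without it the median SE went from 0.197 to 0.743 and the median absolute log2 fold change from 1.02 to 0.648. Of these genes 75.5% kept their sign. In that fit Rabac1, a vesicle traffic protein, went from -5.63 to 2.12 (adjusted p = 0.76).

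**Figure D3:**
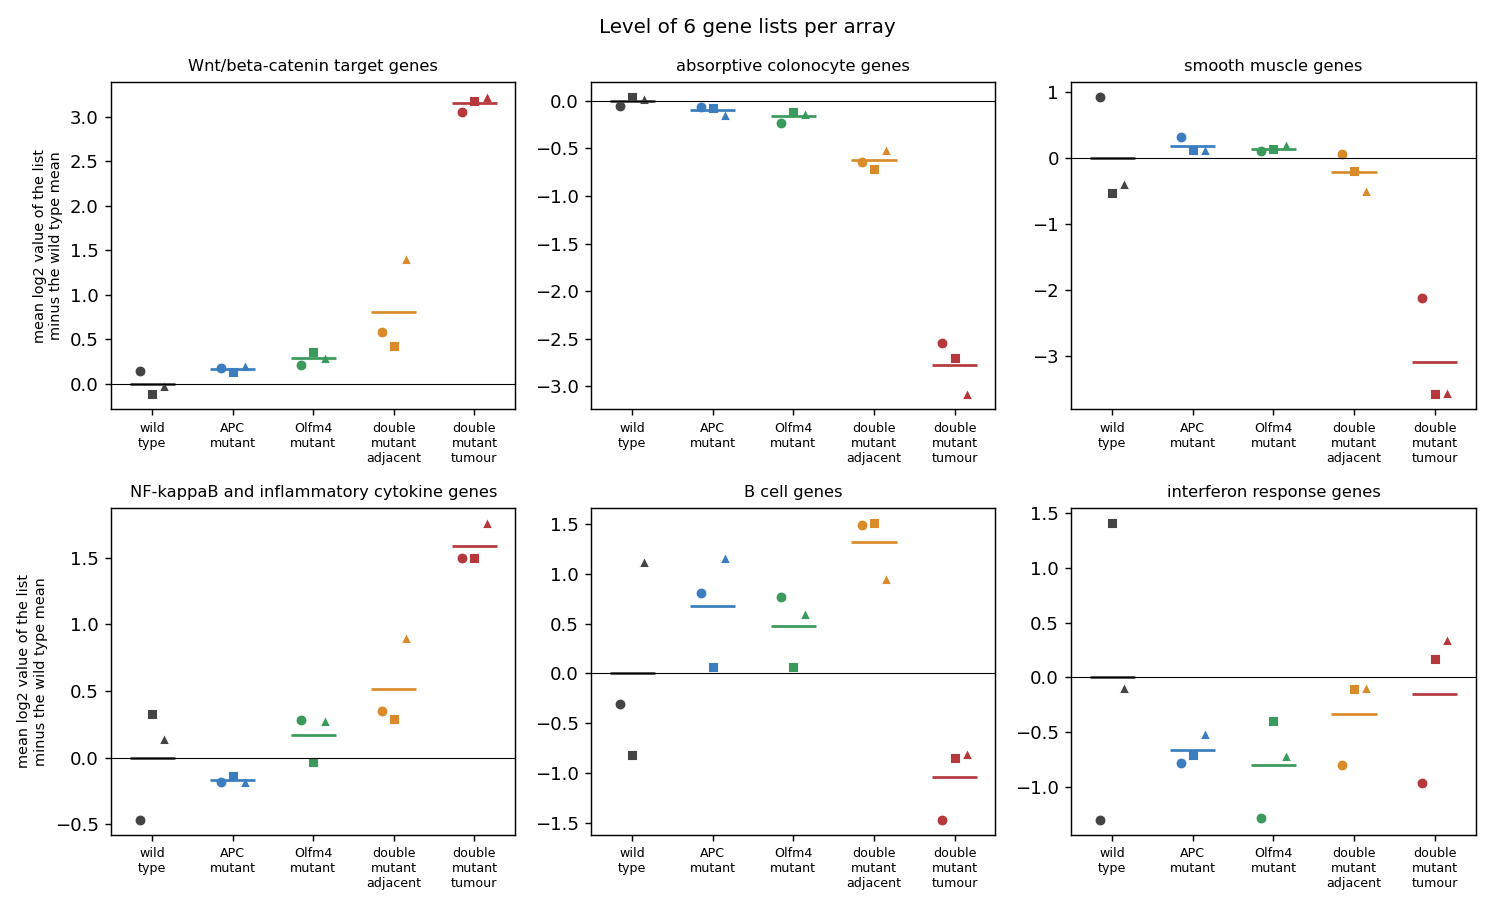
Each panel plots, for each of the 15 arrays, the mean log2 value of the measured genes of a list minus its mean in wild type, against the group, with a line at each group's mean and circle, square and triangle for replicates 1, 2 and 3. Tumour arrays lie highest for Wnt targets and lowest for smooth muscle and absorptive genes, and wild type replicate 2 lies highest for interferon response genes.

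Loss of Olfm4 with intact Apc was examined in Olfm4 mutant against wild type colon. The short-chain dehydrogenase Sdr16c6 was 12.1-fold higher (log2 3.60, SE 0.44, n = 3 per group, adjusted p = 0.0023), the meiotic ubiquitin ligase Ccnb1ip1 4.42-fold (log2 2.15, SE 0.38, adjusted p = 0.01) and the chromatin remodelling subunit Smarcc1 3.72-fold (log2 1.90, SE 0.29, adjusted p = 0.006). The atrial myosin light chain Myl7 was 10.5-fold lower (log2 -3.39, SE 0.83, adjusted p = 0.03), the ribonuclease angiogenin (Ang) 5.84-fold (log2 -2.55, SE 0.67) and the complement chain C1qa 4.7-fold (log2 -2.23, SE 0.48). Other large rises were Zan (2.80), AI467606 (2.26), Tmprss13 (2.12), Ttc5 (2.04), the copper transporter Atp7b (2.03) and Fosb (1.93). Other large falls were Rabac1 (-2.55), Ly6g6c (-2.34), Ms4a4b (-2.29), the integrin Itgb6 (-2.24), secretin (Sct, -2.09), cytidine deaminase (Cda, -2.06) and Get3 (-1.91). Of the named genes called here, 19 of 27 lost the call without some array. Without Olfm4 mutant replicate 2 Rabac1 stood at -1.63 (adjusted p = 0.091) and C1qa at -1.48 (adjusted p = 0.029), with Olfm4 mutant means of 9.06 ± 1.6 and 8.78 ± 1.3 (SD, n = 3). Without Olfm4 mutant replicate 1 Ang stood at -1.53 (adjusted p = 0.047). Myl7 lost its call without any array but wild type replicate 1 (adjusted p from 0.07 to 0.11). Smarcc1 stood at -0.09 (adjusted p = 0.69) in the mean of its probe sets. In total 1440 genes passed (7.92%), 986 higher and 454 lower, or 533 higher and 793 lower after an added cyclic loess normalization.

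Interferon response genes had a median of -0.80 (camera adjusted p = 3.2e-05, adjusted p = 0.86 with an estimated correlation). The antiviral membrane protein Bst2 fell by 1.72 (SE 0.36, adjusted p = 0.018) as 1 of 28 members (1 adjusted over the list alone). Xaf1 at -1.44 (SE 0.54, adjusted p = 0.12), Psmb9 at -1.10 (SE 0.43, adjusted p = 0.14) and Stat2 at -0.87 (SE 0.31, adjusted p = 0.11) did not pass. Without wild type replicate 2, whose interferon genes stood highest of the 15 arrays, the median was -0.05 (adjusted p = 0.24). The Wnt target list did not pass (median 0.21, camera adjusted p = 0.3), but 3 of its 28 genes rose (6 adjusted over the list alone). They were the receptor Ephb3 at 0.94 (SE 0.21), the ubiquitin ligase Znrf3 at 0.93 (SE 0.23) and the Notch ligand Jag1 at 0.78 (SE 0.19), while Bmp4 stood at 0.61 (SE 0.18, adjusted p = 0.054). Of the stem cell list, which did not pass (camera adjusted p = 0.34), Lrig1 rose by 0.98 (SE 0.17) and Tert by 0.79 (SE 0.13), and of the circadian list (camera adjusted p = 0.31) Dbp rose by 1.66 (SE 0.43) and Per3 by 1.47 (SE 0.31).

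The spike-in difference was 1.99 in wild type and 2.64 in Olfm4 mutant arrays. With it as a covariate 20 genes passed, all among the 1440 in the same direction, with Sdr16c6 at 3.93 (adjusted p = 0.044) and AI467606 at 2.19 (adjusted p = 0.048), and 100% of the 1440 kept their sign. Their median absolute log2 fold change went from 0.806 to 0.665 and their median SE from 0.181 to 0.223, so the calls ended through both. The count was 279 without Olfm4 mutant replicate 2, 303 without Olfm4 mutant replicate 3, 350 without wild type replicate 2 and 2236 without wild type replicate 1. Only 33 genes passed in a fit of these 6 arrays alone.

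The heterozygous APC mutation was examined in APC mutant against wild type colon. No gene changed past the threshold by limma (0 called, 1324 genes at an unadjusted p below 0.05, smallest adjusted p = 0.194). Among Wnt target genes Axin2 stood at 0.43 (SE 0.17, adjusted p = 0.64) and Jag1 at 0.59 (SE 0.19, adjusted p = 0.55). Of the interferon response list 0 of 28 genes passed (0 adjusted over the list alone) at a median of -0.65 (camera adjusted p = 3.9e-05, adjusted p = 0.79 with an estimated correlation), with Ifit3 at -1.07 (SE 0.59), Irf7 at -1.03 (SE 0.46) and Bst2 at -0.80 (SE 0.36). Immediate early and heat shock genes had a median of -0.54 with 0 of 16 past the threshold (0 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.79 with an estimated correlation), among them the chaperone Hspa1a at -1.81 (SE 0.71) and Junb at -0.56 (SE 0.22). B cell genes (median 0.67, camera adjusted p = 0.014, Fcmr at 1.49, SE 0.67) and exocrine pancreas genes (median 0.55, camera adjusted p = 0.014) had an adjusted p = 0.79 with an estimated correlation. Enteric neuron and glia genes (median 0.35, camera adjusted p = 0.044) had an adjusted p = 0.86 with an estimated correlation. None of their members passed. The spike-in difference was 1.99 in wild type and 2.16 in APC mutant arrays. Without wild type replicate 1 the count was 188 genes and 11 lists, without wild type replicate 2 it was 0 genes and 1 list, without wild type replicate 3 it was 1 gene and 5 lists, and without APC mutant replicate 1 it was 0 genes and 2 lists. Without wild type replicate 2 the neuron and glia median was -0.10 (adjusted p = 0.79). Interferon response genes stood highest of all arrays in that replicate, which enters the interferon median here too.

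Adjacent tissue of the double mutants was set against wild type colon. Sdr16c6 was 26.4-fold higher (log2 4.72, SE 0.44, n = 3 per group, adjusted p = 0.00024), and the calprotectin subunits of neutrophils and stressed epithelium, S100a8 and S100a9, 13.5-fold (log2 3.75, SE 0.92, adjusted p = 0.0099) and 9.03-fold (log2 3.17, SE 0.96, adjusted p = 0.027). Wif1 was 8.94-fold higher (log2 3.16, SE 0.73) and Ccnb1ip1 9.27-fold (log2 3.21, SE 0.38). The adjacent arrays spread widely in Wif1 (7.33 ± 2.2, SD, n = 3, against 4.17 ± 0.19 in wild type) and S100a8 (10.1 ± 2.2). Without adjacent replicate 3 Wif1 stood at 1.88 (adjusted p = 4e-04), S100a8 at 2.55 (adjusted p = 0.032) and S100a9 at 2.01 (adjusted p = 0.11). Rabac1 was 37.2-fold lower (log2 -5.22, SE 0.64, adjusted p = 0.00034), Ang 21.6-fold (log2 -4.43, SE 0.67) and C1qa 12.9-fold (log2 -3.69, SE 0.48). Pnliprp1 (4.05), Clca4b (3.46), Pnliprp2 (3.01), Fcmr (3.00) and Gp1bb (3.00) were the other largest rises. Ly6g6c (-4.04), Get3 (-3.76), Pknox1 (-3.32), Cda (-3.30), Sct (-3.26), Cpn1 (-3.24) and Rex1bd (-3.05) were the other largest falls. In total 5056 genes passed (27.8%), 3216 higher and 1840 lower, or 2058 higher and 2508 lower after an added cyclic loess normalization, which moved the median of all genes from 0.13 to 0.01.

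Of the absorptive colonocyte list 6 of 20 genes fell and 1 rose (6 and 1 adjusted over the list alone, median -0.41, camera adjusted p = 0.0011, adjusted p = 1 with an estimated correlation). Aqp8 fell by 2.18 (SE 0.22), the guanylin peptides Guca2b and Guca2a by 1.90 (SE 0.29) and 1.30 (SE 0.27), and the brush border gene Ceacam20 by 1.20 (SE 0.28). The Wnt target list missed the threshold (median 0.79, camera adjusted p = 0.072), with 10 of 28 genes higher and 1 lower (14 and 1 adjusted over the list alone). The transcription factor Lef1 rose by 1.69 (SE 0.31), Znrf3 by 1.27 (SE 0.23), Ephb3 by 1.06 (SE 0.21) and Jag1 by 0.96 (SE 0.19). B cell genes did not pass as a list (median 1.20, camera adjusted p = 0.12), but 5 of 12 rose (6 adjusted over the list alone), among them Cd22 by 2.12 (SE 0.37), Cr2 by 2.11 (SE 0.48) and Fcer2a by 1.19 (SE 0.31).

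The spike-in difference was 1.99 in wild type and 4.10 in adjacent arrays. With it as a covariate 0 genes passed by limma (606 at an unadjusted p below 0.05). For the genes called without it the median SE went from 0.19 to 0.506 and the median absolute log2 fold change from 0.824 to 0.37. Of these genes 76.9% kept their sign, so the calls ended through both the wider error and smaller folds. Sdr16c6 stood at 5.78 and Ccnb1ip1 at 2.76 in that fit (adjusted p = 1 for each), while Rabac1 went from -5.22 to 0.19, C1qa from -3.69 to 0.32 and Rex1bd from -3.05 to 0.15. The count was 3184 in a fit of these 6 arrays alone and 3360 after arrays of the same animal were averaged.

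The calls of Olfm4 mutant against wild type and of adjacent tissue against wild type were compared, since both lack Olfm4. They shared 1295 genes in the same direction, 880 higher and 415 lower, and 0 in opposite directions. Independent lists of these sizes would share 174 higher and 45.9 lower genes. The comparisons share their 3 wild type arrays, and 100 simulations of unchanged groups against those arrays shared 0 genes. Unchanged groups gave at most 2 calls in a simulation, so that 0 does not gauge lists of these sizes. Part of the excess may come from the shared wild type arrays, which are too few to be split, and both groups stood above wild type in the spike-in difference. APC mutant against wild type, with 0 calls, shared 0 genes with either.

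Adjacent tissue was set against APC mutant colon, where the added Olfm4 loss is the genotype difference. Adjacent tissue also lay next to a tumour, which the labels do not say of APC mutant colon. Olfm4 loss and nearness to a tumour cannot be told apart here. The antimicrobial lectin Reg3b was 13.1-fold higher (log2 3.71, SE 1.1, n = 3 per group, adjusted p = 0.039), Ccnb1ip1 10.4-fold (log2 3.38, SE 0.38, adjusted p = 0.0011), S100a8 9.41-fold (log2 3.23, SE 0.92) and the stromelysin Mmp10 7.37-fold (log2 2.88, SE 0.82). The adjacent arrays spread widely in Reg3b (8.59 ± 2.4, SD, n = 3, against 4.88 ± 0.02 in APC mutant), S100a8 (10.1 ± 2.2) and Mmp10 (10.3 ± 2). Without adjacent replicate 3 Reg3b stood at 2.61 (adjusted p = 0.15), S100a8 at 2.03 (adjusted p = 0.1) and Mmp10 at 1.74 (adjusted p = 0.091). Each of the 3 also lost its call without any one APC mutant array. Rabac1 was 28.2-fold lower (log2 -4.82, SE 0.64, adjusted p = 0.0014), and the differentiation inhibitor Id1 7.19-fold lower (log2 -2.85, SE 0.44). Clca4b (3.18), Pnliprp1 (3.02, or 2.00 without adjacent replicate 3), Wif1 (2.95, or 1.67 without it), Sdr16c6 (2.93), Gp1bb (2.93) and Pnliprp2 (2.68) were the other largest rises. Ang (-4.21), Get3 (-3.40), C1qa (-3.22), Rnf167 (-3.17), Pknox1 (-3.01), Atp5g2 (-2.79), Pcdh17 (-2.76) and Cda (-2.72) were the other largest falls. In total 3154 genes passed (17.3%), 1798 higher and 1356 lower, or 1089 higher and 1737 lower after an added cyclic loess normalization, which moved the median of all genes from 0.14 to 0.02.

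Absorptive colonocyte genes fell in 5 of 20 cases (6 adjusted over the list alone, median -0.34, camera adjusted p = 4.2e-04, adjusted p = 0.95 with an estimated correlation), with the sodium-proton exchanger Slc9a3 lower by 1.77 (SE 0.48), Aqp8 by 1.71 (SE 0.22), Guca2b by 1.36 (SE 0.29) and Guca2a by 1.29 (SE 0.27). The NF-kappaB and cytokine list did not pass (median 0.54, camera adjusted p = 0.066), with 3 of 28 genes higher and 1 lower (2 and 0 adjusted over the list alone). Cxcl2 rose by 2.25 (SE 0.69, or 1.06 without adjacent replicate 3), Nfkb2 by 0.99 (SE 0.2) and the adhesion molecule Icam1 by 0.74 (SE 0.18), and Relb fell by 0.78 (SE 0.25). Of the Wnt target list (median 0.53, camera adjusted p = 0.12) 4 of 28 rose and 2 fell (9 and 2 adjusted over the list alone), with Wnt6 higher by 1.17 (SE 0.24), Ephb3 higher by 0.97 (SE 0.21) and the crypt transcription factor Sox9 lower by 1.07 (SE 0.25). The spike-in difference was 2.16 in APC mutant and 4.10 in adjacent arrays, and with it as a covariate 0 genes passed by limma (420 at an unadjusted p below 0.05). For the 3154 genes called without it the median SE was then 0.441 against 0.183. Their median absolute log2 fold change went from 0.774 to 0.283 and 72.9% kept their sign, so the calls ended through both. In that fit Rabac1 stood at 0.15, C1qa at 0.46, Id1 at 0.22, Pcdh17 at 0.10 and Relb at 0.38. The count of called genes was 1628 without APC mutant replicate 1, 2005 without APC mutant replicate 2, 1578 without adjacent replicate 3 and 1651 after arrays of the same animal were averaged.

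Adjacent tissue was set against Olfm4 mutant colon, where the added APC mutation is the genotype difference. Nearness to a tumour, which the labels give only for adjacent tissue, cannot be told from that mutation. The hepcidin gene Hamp2 was 7.26-fold higher (log2 2.86, SE 0.38, n = 3 per group, adjusted p = 0.027), the inhibitory leukocyte receptor Lair1 4.33-fold (log2 2.12, SE 0.23, adjusted p = 0.0059) and Rinl 3.64-fold (log2 1.86, SE 0.19, adjusted p = 0.0059). The endothelial receptor Notch4 (1.39), Tmem229b (1.14), Rpap3 (1.10) and Pate14 (0.78) were also higher, and the proteoglycan syndecan 4 (Sdc4) was lower by 1.01 (SE 0.15, adjusted p = 0.04). These were the 8 genes that passed by limma, against 2960 at an unadjusted p below 0.05, and after an added cyclic loess normalization 5 were higher and 2 lower. Aqp8 stood at -1.34 (SE 0.22, adjusted p = 0.051), Guca2b at -1.13 (SE 0.29, adjusted p = 0.087) and Cd22 at 1.37 (SE 0.37, adjusted p = 0.099).

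By camera 8 lists passed, although 0 of their members passed over all genes. The absorptive colonocyte list had a median of -0.26 (adjusted p = 5.9e-04, 5 lower adjusted over the list alone) and the circadian clock list a median of -0.52 (adjusted p = 0.018, 1 lower adjusted over the list alone), each with an adjusted p = 0.51 with an estimated correlation. The other 6 had an adjusted p = 0.89 with an estimated correlation. These were immediate early and heat shock genes (median -0.37, adjusted p = 0.0095), B cell genes (median 1, adjusted p = 0.013), T cell genes (median 0.45, adjusted p = 0.018), and Wnt target genes (median 0.34), adipocyte genes (median -0.43) and smooth muscle genes (median -0.26) at an adjusted p = 0.034 each. The spike-in difference was 2.64 in Olfm4 mutant and 4.10 in adjacent arrays, and with it as a covariate 0 genes passed by limma (423 at an unadjusted p below 0.05). All 8 genes kept their sign (100%). Their median absolute log2 fold change went from 1.26 to 0.827 and their median SE from 0.182 to 0.342, with Hamp2 at 3.81 (SE 0.75), Rinl at 1.92 (SE 0.42) and Notch4 at 0.58 (SE 0.35) in that fit, so the calls ended through both. The immediate early and Wnt target medians stood at 0.39 and 0.00. The count was 0 without Olfm4 mutant replicate 3, 774 without Olfm4 mutant replicate 2, 17 without adjacent replicate 1, 3 without adjacent replicate 3 and 5 without Olfm4 mutant replicate 1. With array weights it was 3308, and Olfm4 mutant replicate 3 had the largest weight, 3.59. Of the 8 genes 3 stayed called with animal as a random block, and 3 after arrays of the same animal and tissue were averaged.

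The interaction asks whether the effect of the APC mutation differed between colon with and without Olfm4. Its double mutant tissue alone lay next to a tumour, which cannot be told from an interaction of the genotypes. No gene passed by limma (0 called, 1901 at an unadjusted p below 0.05, smallest adjusted p = 0.0778), and Axin2 stood at -0.92 (SE 0.25, adjusted p = 0.36). By camera 5 lists passed, with 0 members past the threshold and an adjusted p = 0.89 with an estimated correlation for each. Interferon response genes had a median of 1.15 (adjusted p = 1.4e-04), with Gbp3 at 1.87 (SE 0.73), Ifit3 at 1.70 (SE 0.83), Irf7 at 1.29 (SE 0.65) and Ddx58 at 1.06 (SE 0.53). NF-kappaB and cytokine genes had a median of 0.30 (adjusted p = 0.02), absorptive colonocyte genes -0.27 (adjusted p = 0.021), smooth muscle genes -0.43 (adjusted p = 0.021) and enteric neuron and glia genes -0.56 (adjusted p = 0.032). The spike-in difference rose by group as above, from 1.99 in wild type to 4.10 in adjacent arrays. The count of genes was 93 without wild type replicate 1, 52 without Olfm4 mutant replicate 2 and 2 without adjacent replicate 1. The count of lists was 0 without wild type replicate 2, 1 without Olfm4 mutant replicate 2, 2 without adjacent replicate 3, 3 without wild type replicate 3, 8 without APC mutant replicate 2 or 3, 9 without Olfm4 mutant replicate 1 and 10 without adjacent replicate 1.

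**Figure D4:**
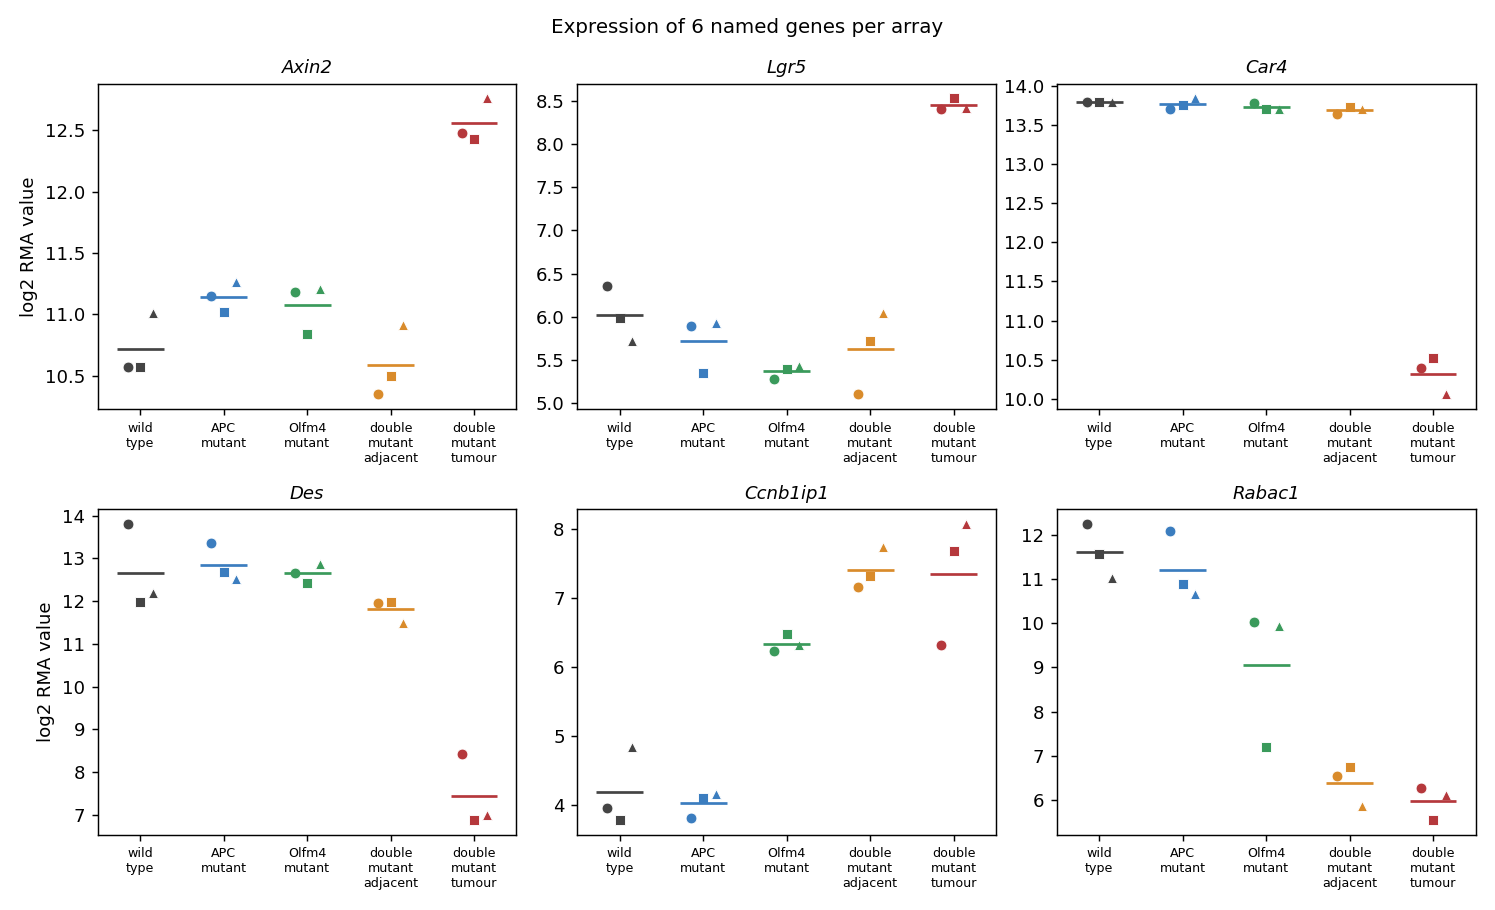
Each panel plots the deposited log2 value of a gene on each of the 15 arrays against the group, with a line at each group's mean and circle, square and triangle for replicates 1, 2 and 3. Axin2 and Lgr5 are highest and Car4 and Des lowest in the 3 tumour arrays, Ccnb1ip1 is higher in the 9 arrays without Olfm4 than in the other 6, and Rabac1 falls from wild type through adjacent to tumour arrays.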

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

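Of the tests in this part, those on the pool, on the share of the muscle wall, on slopes in adjacent against APC mutant and in tumour against wild type, and on calls kept with the spike-in covariate were chosen after the result was seen, the smooth muscle test used that covariate, added after the control probe sets were seen, but was set before its value was seen, and the others were chosen before.

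By camera 5 gene lists passed in the interaction, which asks whether the effect of the APC mutation differs between colon with and without Olfm4. Nearness of the double mutant tissue to a tumour cannot be told from it. The adjusted p was 0.00014 for interferon response genes, 0.02 for NF-kappaB and inflammatory cytokine genes, 0.021 for absorptive colonocyte genes, 0.021 for smooth muscle genes and 0.032 for enteric neuron and glia genes. With an estimated correlation it was 0.89 for each, 0 of their members passed, and without wild type replicate 2 the count of lists was 0. In control data outside the gene comparisons, the 3-prime minus 5-prime difference of the added bacterial RNAs stood above its wild type level of 1.99, at 2.64 in Olfm4 mutant, 4.10 in adjacent and 5.01 in tumour arrays.

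Weaker labelling towards the 5-prime end could account for part of the calls, since the added RNAs carry no mouse biology. For each called gene the slope on the spike-in difference within groups was compared in sign with the fold change. The signs matched in a share of 0.883 for adjacent against APC mutant (0 of 100 permutations as high). For adjacent against wild type the share was 0.84 (5 of 100, highest permuted share 0.871). That is just at the limit of 5 set beforehand, so it is hardly firmer than the next ones. Shares of 0.773 for Olfm4 mutant against wild type (7 of 100), 0.733 for tumour against wild type (7 of 100) and 0.588 for tumour against adjacent (19 of 100) do not settle it. Of adjacent against wild type calls with another bright probe set, 422 of 1076 (39.2%) showed there less than 0.25 of the fold change or the opposite sign. Of tumour against adjacent calls 50 of 916 (5.46%) did (odds ratio 11.2, one-sided Fisher's exact p = 2.6e-78), and 119 of 329 (36.2%) did in Olfm4 mutant and 481 of 1755 (27.4%) in tumour against wild type. The Fisher's test counts genes of the same arrays, which are not independent, so its p does not measure replication between animals. Fold sizes differed too, with a median absolute log2 fold change of all called genes of 0.824 in adjacent against wild type and 0.993 in tumour against adjacent. In tumour against adjacent tissue 2025 genes kept their call with the spike-in covariate, so a linear effect of the spike-in difference, as fitted, does not account for those. Its slope is fitted within groups, where the spread was widest in Olfm4 mutant arrays (SD 0.525, with replicate 2 at 3.25). A labelling effect that differs from that slope is not excluded. In adjacent and tumour against wild type the covariate nearly coincides with the groups, so calls lost with it are partly lost power, while in Olfm4 mutant against wild type, where 20 of 1440 calls stayed, it recovered 44% of simulated changes of log2 1 (64% without it) and the median absolute log2 fold change went from 0.806 to 0.665 with 100% of signs kept, which does not settle the cause, and an effect of genotype on the other calls cannot be told from run order.

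Olfm4 mutant replicate 3 may be a pool of replicates 1 and 2, as the joined digits of its number suggest. It ranked 1 of 15 arrays in closeness to a mixture of its group mates (residual ratio 0.455, next 0.595), and 93.9% of the 703 genes that differ by at least 1 between its mates lay between them. A separate animal with intermediate expression would look the same, as would one with labelling between that of its mates, and neither was tested. Replicate 3 did lie between its mates in the spike-in difference (2.29, 3.25 and 2.40 in replicates 1, 2 and 3). The same held for the Gapdh difference (0.753, 2.76 and 0.971). If it is a pool, the Olfm4 mutant group holds 2 animals, and without this array 303 genes differ from wild type.

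The fall of smooth muscle genes in tumours may reflect a smaller share of the muscle wall in the tumour pieces. Enteric neuron and glia genes, which sit in the same wall, had a median of -1.23, as that explanation predicts. With the spike-in covariate the smooth muscle median was -2.65, so a linear adjustment for the spike-in difference did not remove the fall. The slope of that adjustment is fitted within groups, where the spread was widest in Olfm4 mutant arrays (SD 0.525). Weaker labelling that acts otherwise in these tissues is therefore not excluded. Lower expression within muscle cells of the tumour was not tested.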

How the results depend on the processing

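The alternatives with the spike-in covariate and the blocked list tests were added after the data were seen. Results for named genes and lists kept direction and side of the threshold in 4067 fits, lost their call in 578, gained one in 24, changed sign without a call in 6 and turned with a call in 22. Unless a reason is given, the cause was not tested.

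With animal as a fixed replicate block tumour against adjacent tissue had 5183 genes and 15 lists, and with adjacent and tumour arrays in a pairing block 4915 genes and 15 lists. Circadian clock genes gained a call, and Itln1, Rgmb and (in pairs) Ccl20 lost theirs. The block changed no other call of a named gene or list. With animal as a random block the 8 genes of adjacent against Olfm4 mutant became 3.

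Leaving out an array gave the following ranges of genes and lists called. Olfm4 mutant against wild type had 279 to 2236 genes and 1 to 6 lists (1440 and 1 with all arrays), APC mutant against wild type 0 to 188 and 1 to 11 (0 and 5), and adjacent against wild type 3448 to 5032 and 1 to 5 (5056 and 1). Adjacent against APC mutant had 1578 to 2826 genes and 1 to 4 lists (3154 and 1), adjacent against Olfm4 mutant 0 to 774 and 2 to 13 (8 and 8), tumour against adjacent 3914 to 4570 and 13 to 15 (5112 and 14), tumour against wild type 7936 to 8470 and 12 to 17 (8996 and 16), and the interaction 0 to 93 and 0 to 10 (0 and 5). Of the named genes called, the call ended without some array in 2 of 32 in adjacent against wild type, 9 of 31 in adjacent against APC mutant, 8 of 8 in adjacent against Olfm4 mutant, 15 of 99 in tumour against adjacent and 0 of 23 in tumour against wild type. The enteric neuron and glia median of APC mutant against wild type went from -0.10 without wild type replicate 2 to 0.83 without wild type replicate 1.

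With a correlation estimated from the data 2 lists passed in tumour against adjacent, 1 in tumour against wild type and 0 in each other comparison. A fit of only the groups compared, which leaves fewer degrees of freedom, called 33 genes in Olfm4 mutant against wild type, 3184 in adjacent against wild type and 1 in adjacent against Olfm4 mutant. Array weights from 0.333 to 3.59 gave 2779 genes in Olfm4 mutant against wild type, 1 in APC mutant against wild type, 4896 in adjacent against APC mutant, 3308 in adjacent against Olfm4 mutant and 22 in the interaction. The smallest weight went to wild type replicate 1. The largest went to Olfm4 mutant replicate 3, the possible pool, which lies close to a mixture of its group mates. With arrays of an animal averaged, which leaves fewer samples, the counts were 824 for Olfm4 mutant against wild type, 3360 for adjacent against wild type, 1651 for adjacent against APC mutant and 3286 for tumour against adjacent.

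Only genes above the median mean, which tests fewer genes by construction, gave 3329 in tumour against adjacent, 5898 in tumour against wild type, 135 in adjacent against Olfm4 mutant and 1 in the interaction. A trend and robust prior gave 81 in adjacent against Olfm4 mutant, and cyclic loess 1 in the interaction. The most variable probe set gave 432 in adjacent against Olfm4 mutant and 6 in the interaction, and the mean of probe sets 1 in the interaction and 2 lists in adjacent against APC mutant.

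Probe set choice turned Apc, whose probe sets move apart. The most variable one gave -1.29 in Olfm4 mutant against wild type, -2.00 in adjacent against wild type, -0.21 in tumour against adjacent and -2.21 in tumour against wild type, and the mean gave -0.37 in adjacent against wild type and -0.32 in tumour against wild type. In APC mutant against wild type another pair of Apc probe sets gave -0.06 each, and the remaining one gave 0.05. Smarcc1 in Olfm4 mutant against wild type was -0.09 in the mean, and Nfkb2 in adjacent against APC mutant -0.39 with the most variable probe set.

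The spike-in covariate nearly coincides with the groups in adjacent and tumour against wild type, and less so in Olfm4 mutant against wild type. With it the counts of genes were 20 for Olfm4 mutant against wild type, 2144 for tumour against adjacent, 1 for tumour against wild type and 0 for adjacent against wild type, APC mutant and Olfm4 mutant. Lists called were 6 for Olfm4 mutant against wild type, 8 for adjacent against wild type, 11 for adjacent against APC mutant and 9 for the interaction. In adjacent against wild type Rabac1 turned to 0.19, C1qa to 0.32 and Rex1bd to 0.15. In adjacent against APC mutant Rabac1 turned to 0.15, C1qa to 0.46, Id1 to 0.22, Pcdh17 to 0.10 and Relb to 0.38. In adjacent against Olfm4 mutant the immediate early and heat shock median turned to 0.39 and the Wnt target median to 0.00. In tumour against wild type Rabac1 turned to 2.12, the B cell median to 0.70 and the cell cycle median to -0.08.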

Other observations

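The genes and tests of the next paragraphs were chosen after their values were seen, except the test near Olfm4 and the splits. Several genes moved against their list in tumours compared with adjacent tissue. Among stem cell genes the growth factor receptor inhibitor Lrig1 fell by 0.89 (SE 0.17, limma adjusted p = 0.0018) and the BMP co-receptor Rgmb by 0.81 (SE 0.27, adjusted p = 0.043, 0.051 with animal as a block and 0.061 in a pairing block). Among absorptive genes the sodium-proton exchanger Slc9a3 rose by 1.52 (SE 0.48), and among enteroendocrine genes the transcription factor Isl1 rose by 2.30 (SE 0.33). Tuft cell genes, which did not pass as a list, split. The kinase Dclk1 fell by 2.35 (SE 0.16, adjusted p = 7.8e-07) and the taste channel Trpm5 by 1.48 (SE 0.46), while the actin regulator Avil rose by 3.33 (SE 0.41) and the leukotriene protein Alox5ap by 0.69 (SE 0.24). The plasma cell regulator Prdm1 rose by 0.63 (SE 0.16) and the chemokine Ccl20 fell by 1.05 (SE 0.35, adjusted p = 0.038, 0.058 in a pairing block).

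Epithelial antimicrobial genes split too, with 5 of 19 higher and 5 lower. Of those higher, S100a8 also stands in the neutrophil list, which rose here, and bulk tissue does not show which cells the RNA came from. The acute phase protein Saa3 rose by 4.17 (SE 0.94), lipocalin 2 (Lcn2) by 3.23 (SE 0.71), S100a9 by 2.89 (SE 0.96), S100a8 by 2.85 (SE 0.92) and lactoferrin (Ltf) by 2.30 (SE 0.44). Saa2 fell by 0.95 (SE 0.2), Saa1 by 0.81 (SE 0.096), Reg4 by 0.71 (SE 0.18), Dmbt1 by 0.65 (SE 0.17) and the antibody transporter Pigr by 0.58 (SE 0.096). Of the circadian clock genes 5 of 15 fell, Nr1d1 by 2.18 (SE 0.34), Dbp by 1.63 (SE 0.43), Per3 by 1.38 (SE 0.31), Hlf by 1.21 (SE 0.35) and Arntl by 0.80 (SE 0.27), and the hour of sampling is not given in the sources used here.

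Ccnb1ip1 and Ttc5, which lie on the chromosome of Olfm4 in the assembly GRCm38.p6, were higher in all 9 arrays without Olfm4 than in any of the 6 with it. For Ccnb1ip1 the lowest of the 9 was 6.23 and the highest of the 6 was 4.85 on the log2 scale (means 7.04 ± 0.71 and 4.11 ± 0.39, SD), and for Ttc5 these were 7.93 and 7.58 (means 8.4 ± 0.24 and 6.4 ± 0.76). Between them and Olfm4 lie 314 and 315 measured genes. Because the mice are strain hybrids, DNA of another strain carried along with the targeted gene could change such genes. Among the 100 measured genes nearest to Olfm4, 11 (11%) were called in Olfm4 mutant against wild type, against 7.9% of 18092 other genes (odds ratio 1.44, one-sided Fisher's exact p = 0.17), which does not settle it.

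Whether the counts could arise from any grouping of the arrays was tested by splitting the 6 arrays of each comparison. All 10 splits were made, too few for a share under 0.05. Each other split puts arrays of both groups on both sides, so a large difference of any cause widens the error. Low counts in the other splits were therefore to be expected, and they tell nothing of the cause, run order included. The real split alone (1 of 10) gave its count in Olfm4 mutant against wild type (1440, highest other 2), adjacent against wild type (5056, highest other 1), adjacent against APC mutant (3154, highest other 2), adjacent against Olfm4 mutant (8, highest other 1), tumour against adjacent (5112, highest other 1) and tumour against wild type (8996, highest other 2). In tumour against adjacent tissue 4 splits part all pairs of arrays, and the highest of the other 3 was 0. In APC mutant against wild type and the interaction the real count is 0, which each split must reach (10 of 10, and 100 of 100 regroupings of the 12 arrays), so the splits test nothing there. In APC mutant against wild type the split of wild type 1, wild type 2 and APC mutant 1 from the rest gave 365, that of wild type 1, APC mutant 1 and APC mutant 3 gave 259. In the interaction regroupings gave up to 3061. They move the adjacent arrays, which differed from wild type in 5056 genes, between groups, so high counts there can come from that difference. The 365 and 259 genes in APC mutant against wild type point to some structure of those samples. The split with 365 genes parts the arrays with the 3 lowest spike-in differences (1.89, 1.93 and 2.01) from the 3 highest (2.06, 2.23 and 2.32), while that with 259 does not follow them.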
